A study of Caenorhabditis elegans with 4 samples.

How the data were processed

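Chromatin immunoprecipitation followed by sequencing was carried out on Caenorhabditis elegans embryos of strain OP32, which carries a dpy-27 transgene. Per the labels, worms were grown at 20 degrees C, embryos were fixed in 2% formaldehyde for 30 min, chromatin was sheared to between 200 and 800 bp, and an anti-GFP antibody was used for the precipitation. There were 2 ChIP libraries and 2 input libraries, numbered 1 and 2, and the labels describe each input as DNA of the same preparation. Nothing in the labels says that the numbers stand for separate cultures. P-values of the bin tests and of the X share therefore measure only the spread between these libraries, which may be technical. In edgeR that spread is partly pooled over bins, so a bin can be called where the ChIP replicates differ. Binomial, Fisher and shuffle tests take peaks, windows, copies or sites as units, so their p-values hold no spread between libraries.

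The deposited files were of 2 kinds. The read files hold one line per sequenced read with its ELAND match of up to 2 mismatches, and the deposited positions were turned into counts of reads here. The peak files hold regions called by PeakSeq in each ChIP replicate against its input, per the format description deposited with the series. In these files the authors gave the count of ChIP tags per region, the input tags scaled to the ChIP library (a rounded score), the excess of tags (a score), the fold of ChIP over scaled input (a ratio) and a Benjamini-Hochberg corrected q-value. Peak calls were made per replicate, as the deposited lists show. The genome build, the aligner version and the PeakSeq version are not given in the sources used here. All coordinates are those of the deposited files.

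ChIP replicate 1 held 19714807 reads of 27 bases, of which 5.73% had a unique match and 88.0% had no match. Input replicate 1 held 8043973 reads of 27 bases with 63.8% unique. ChIP replicate 2 held 1718168 reads of 34 bases with 55.0% unique, and input replicate 2 held 3181817 reads of 34 bases with 76.9% unique. Unique nuclear reads numbered 1126705 and 942606 in the ChIP libraries and 5121763 and 2440171 in the inputs. Of these, 84.1% and 82.8% in ChIP and 94.4% and 90.3% in input lay at distinct positions and strands. Only 37.8% of the unique reads of ChIP replicate 1 matched without a mismatch, against 80.8%, 90.3% and 90.6% in input replicate 1, ChIP replicate 2 and input replicate 2. At this depth the median autosomal 1 kb bin held 10 and 9 reads in the ChIP libraries and 46 and 24 in the inputs. Intervals are 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

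Every unique nuclear read was counted once, at its 5' end moved 100 bp inward, in 1 kb bins. Bins were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM, filterByExpr, Benjamini-Hochberg 0.05) under R 4.3.3, with DESeq2 1.42.0 as an alternative. Standard errors of bin fold changes were derived from the F statistic. On counts simulated from the real bins over 82667 bins, the step called 14% of 50 bins changed 2-fold, 94% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 4 false calls among 158. All simulated bins shared 1 dispersion (0.03137), without pair effects or regions raised in 1 library. The number of false calls need therefore not hold for the real bins. The X chromosome was tested as a set of bins with camera. Values per pair are differences of log2 CPM (edgeR) with a prior count of 2. The share of reads on X was compared by an exact permutation test, which with 2 against 2 cannot give a two-sided p under 0.333.

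Peak shares on X were set against chromosome length with exact binomial tests, where chromosome length was the last position covered by a read. Overlap meant at least 1 shared base and was set against 1000 shuffles of list 2 within chromosomes. Reads in peaks were also recounted after extension to 200 bp. With at most 3 reads kept per position and strand, the recount equalled the deposited tag count exactly in 94.6% of replicate 1 peaks and 89.3% of replicate 2 peaks. Folds given here as counted with 1 read per position used reads at distinct positions, autosomal totals as the scale and a prior count of 1.

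No genome sequence of the files' build was used. The sequence was instead rebuilt from the reads and their listed substitutions. This covered 75.5% of 100280224 bases, with 0 positions at which reads disagreed about the reference base. The 12 bp sequence TCGCGCAGGGAG, the published consensus of sites that recruit the complex to X, was searched on both strands with up to 2 mismatches. Peaks of both lists were merged, those with at least 80% of their bases rebuilt were kept, and each was given 10 random windows of equal length outside peaks on the same chromosome. All 8-mers were tested in the same way with one-sided Fisher exact tests. The 8-mer step put a planted sequence first on simulated data, among 32890 8-mers tested, of which 2 passed. Simulated peaks and windows were drawn alike from random bases, without any difference in base composition. The number of 8-mers passing there need therefore not hold for real peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Biopython 1.88 were used.

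The gene table at hand is of assembly WBcel235, and the files name no build, so no peak was assigned to a gene. The planned comparisons of promoters, of peaks near gene starts and of gene lists were therefore not made, and 1 kb bins took the place of promoters for the X against autosome comparison, a choice made after the data were seen. The gene lists fixed beforehand (dosage compensation complex, sex determination, other condensin and cohesin, ribosomal proteins, proteasome, histones, small RNA biotypes, lineage factors, Hox, heat shock, collagens, neuropeptides, sperm proteins, vitellogenins, chemoreceptors) gave no result for the same reason. The tagged gene was sought through raised input depth rather than by position, and unc-119 was not located. Peaks named in the text followed a rule set before the data were examined: the 10 X peaks and the 10 autosomal peaks with the lowest deposited q in replicate 1 among those overlapped by a replicate 2 peak. Other peaks and regions were chosen after their values were seen.

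Regions of raised depth were found as runs of at least 4 bins of 1 kb, with 1 read kept per position, that were at least 3 times the autosomal median in both inputs or at least 2.5 times the mean of the other 3 libraries in 1 ChIP library. Reads without a match were searched for the first or last 20 bases within short probes of GFP, the chloramphenicol resistance gene cat and the ampicillin resistance gene bla, and their numbers were scaled to 1000000 unique nuclear reads. Because each input shares its preparation with the ChIP library of the same number, the numbers pair the libraries. Deviations from the group means correlated at -0.04 over bins between same-numbered libraries. Alternatives covered duplicate reads, thinning, left-out libraries, bin size, scaling, GC offsets, the replicate block, the low-count filter, the test, read shift, peak score, overlap and mismatches.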

Results

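DPY-27 is a condensin subunit of the C. elegans dosage compensation complex, which binds both X chromosomes of hermaphrodites and lowers their expression. The study set out to locate its binding sites in embryos through a GFP-tagged protein. The data were 2 ChIP libraries and 2 input libraries, numbered in pairs by preparation. Unique nuclear reads numbered 1126705 and 942606 in ChIP replicates 1 and 2, and 5121763 and 2440171 in the inputs. Coordinates are as deposited, and the genome build is not given in the sources used here.

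The X chromosome was over-represented in both ChIP libraries. It received 22.0% of reads in ChIP replicate 1 (exact interval 21.9 to 22.1%) and 20.5% in ChIP replicate 2 (20.4 to 20.5%), against 18.2% and 18.6% in the inputs. X made up 17.7% of the covered genome length. The group means were 21.2% ± 1.09 (SD, n = 2) in ChIP and 18.4% ± 0.278 (SD, n = 2) in input. ChIP exceeded input 1.21-fold in the first pair and 1.10-fold in the second. No autosome exceeded 1.01-fold in either pair, and III had the lowest ratio, 0.901, in the first pair. The reads of III include a region, described further on, at 31.7 times the autosomal median in input replicate 1 and 8.83 times in ChIP replicate 1. This lowers the ratio of III. By the median bin log2 fold change over all libraries III was not lowest, at -0.03 against -0.06 on II. Both ChIP shares lay above both input shares, and the two-sided exact permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow.

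**Figure D1:**
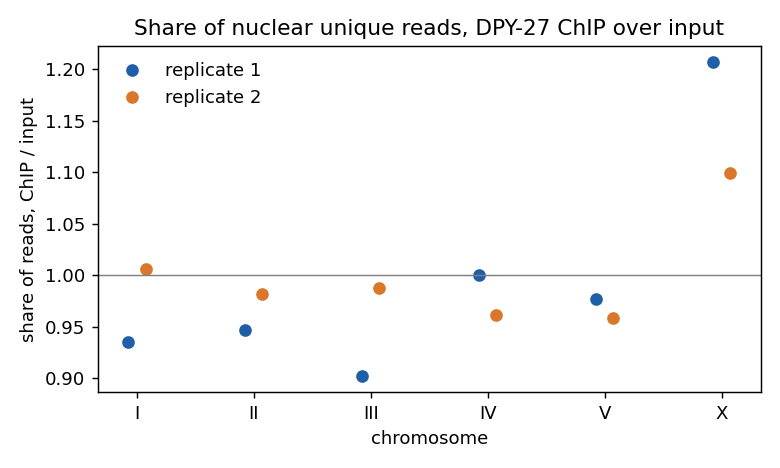
Share of nuclear unique reads on each chromosome (x axis) in ChIP divided by the share in the paired input (y axis, ratio), with 1 point per replicate pair and a grey line at 1. The X points lie at 1.21 and 1.10, above every autosome in both pairs.

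The sites of strongest enrichment were narrow and mostly on X. Of 85710 bins of 1 kb, 134 were higher in ChIP (edgeR, adjusted p under 0.05), 103 of them among the 16276 X bins and 31 among the autosomal ones. The bin at X 11094001 to 11095000 had the largest rise on X, a log2 fold change of 5.41 (SE 0.79, adjusted p = 1.08e-07 by edgeR), and reached 5.41 and 5.04 in the pairs. Bins at X 8036001 and X 14525001 rose by 4.72 (SE 0.71) and 4.86 (SE 0.77) on the log2 scale. Of the 103 X bins, 93 were at least 2-fold higher in both pairs and 92 touched a deposited peak.

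Autosomal calls agreed less well between the replicates. Of the 31 autosomal bins, 28 touched a deposited peak, a share like that on X, but 6 were at least 2-fold higher in both pairs and 11 lay in regions of raised depth described further on. The bin at IV 15691001 held 188 reads in ChIP replicate 1 and 10 in replicate 2, against 37 and 23 in the inputs. Bins lower in ChIP numbered 6 by edgeR and 14 by DESeq2, all on autosomes. At an unadjusted p under 0.05, 5220 of 85710 bins passed by edgeR, and a share of 0.05 would pass with no difference at all. Counts at this unadjusted threshold, here and below, are therefore not counts of changed bins. With the replicate number as a block 72 bins were higher, 65 of them on X, and DESeq2 called 80, all on X. GC offsets raised the count to 221, with 177 on X, and GC offsets with the block gave 207, with 166 on X. The count rested on every library: it was 0 without ChIP replicate 1 or without ChIP replicate 2 by edgeR, with 5202 and 4973 bins at an unadjusted p under 0.05, 5 without input replicate 1 and 41 without input replicate 2.

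A low, chromosome-wide rise on X accompanied the peaks. The median bin log2 fold change was 0.18 on X and -0.03 on autosomes, and the difference was 0.29 in the first pair and 0.11 in the second. Between 56.8% and 68.4% of X bins lay above the autosomal median. At over 2 kb from any deposited peak the difference was still 0.26 and 0.11 in the pairs, and at over 10 kb it was 0.26 and 0.09. Tested as a set, X bins were higher with the preset correlation of 0.01 (camera p = 6.48e-07, and 5.74e-07 with the replicate number as a block). With an estimated correlation the call held without the block (p = 0.0457) and not with it (p = 0.162).

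The authors' peak lists were dominated by X in both replicates. The list of replicate 1 held 560 peaks with 340 on X, or 60.7% (exact interval 56.5 to 64.8%), which was 3.44 times the X share of length (exact binomial p = 1.11e-113). The list of replicate 2 held 252 peaks with 160 on X, or 63.5% (57.2 to 69.4%), 3.59 times the share of length (exact binomial p = 2.48e-58). Density on X was 19.2 and 9.03 peaks per Mb. Among autosomes it ran from 0.796 per Mb on I to 3.99 per Mb on III in replicate 1, and from 0.508 per Mb on III to 1.63 per Mb on V in replicate 2. X peaks were short, with median widths of 260 and 308 bp.

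X peaks recurred between replicates more often than autosomal ones. Of the 160 X peaks of replicate 2, 102 (63.8%) overlapped a replicate 1 peak, against 21 of 92 autosomal peaks (22.8%; Fisher exact test, two-sided p = 3.87e-10). In all, 123 of 252 were shared. In 1000 shuffles the mean was 2.14 and the maximum 8 (permutation p = 0.001, the smallest they can give). Of the 560 replicate 1 peaks, 22.0% overlapped a replicate 2 peak, 30.0% of those on X and 9.55% of the autosomal ones. X peaks found in replicate 1 alone, 238 in number, had a median ChIP to input fold of 2.06 in replicate 2, counted with 1 read per position, whereas the 199 autosomal peaks found in replicate 1 alone had 1.10. At least 1.5-fold enrichment in replicate 2 was seen for 172 of those 238 X peaks and 47 of those 199 autosomal peaks.

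**Figure D2:**
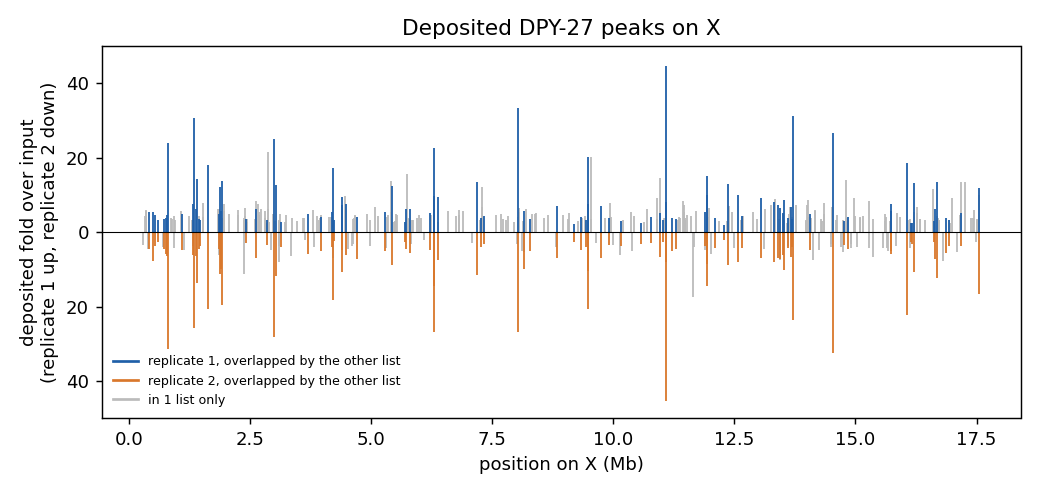
Deposited peaks along X (x axis, Mb), with the authors' fold over input drawn upwards for replicate 1 and downwards for replicate 2 (y axis), coloured where the other list has an overlapping peak and grey where it has none. The highest line of both replicates is the peak at 11093745, with deposited folds of 44.6 and 45.4.

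The 10 best shared X peaks were spread along the chromosome. In the authors' lists their folds ran from 12.3 to 44.6 in replicate 1 and from 8.79 to 45.4 in replicate 2. The strongest by q was X 14525383 to 14526679, with 354 ChIP tags against 14 scaled input tags in replicate 1 (q = 2.80e-83) and 257 against 8 in replicate 2 (q = 2.06e-62). The peak at X 11093745 to 11094516 had 309 tags against 7 in replicate 1 and 249 against 6 in replicate 2. Others lay at X 13700549, X 8036006, X 5429172, X 6296135, X 16681562, X 2996582, X 11936858 and X 1344749. Counted with 1 read per position, the 10 peaks were 8.49-fold to 27.4-fold over input in replicate 1 and 9.08-fold to 25.9-fold in replicate 2.

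The 10 best shared autosomal peaks were weaker and lay where the inputs were already deep. Their deposited folds ran from 2.32 to 4.47 in replicate 1 and from 2.61 to 7.12 in replicate 2, and mean input depth over them was between 4.13 and 159 times the autosomal median. With every read counted, in place of the at most 3 per position that the deposited tags amount to in most peaks, their folds were 0.591 to 3.68 in replicate 1, under 1 for 4 of the 10, and 1.20 to 2.73 in replicate 2. Counted with 1 read per position, they were 2.10-fold to 5.01-fold in replicate 1 and 1.91-fold to 2.61-fold in replicate 2. That count is limited where inputs are deep, so the enrichment of these peaks depends on how repeated reads are counted. The 10 peaks were at I 15064010, III 7446538, V 5283993, IV 11070899, III 931225, IV 13549243, I 3171484, V 12509898, II 14337589 and I 933311. Among all 21 shared autosomal peaks 18 had input depth over 3 times the median, against 4 of 102 shared X peaks.

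Signal fell steeply with distance from the shared X peaks. Within 250 bp of their centres ChIP was 6.23 times input in replicate 1 (counting interval 5.98 to 6.49) and 7.52 times in replicate 2 (7.10 to 7.97). Between 500 and 1000 bp the ratio was 1.46 and 1.20. It then levelled off above 1, at 1.23 (1.22 to 1.24) and 1.09 (1.08 to 1.11) between 20000 and 50000 bp. Around the 20 shared autosomal peaks outside raised regions the ratio at that distance was 1.02 and 0.964.

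**Figure D3:**
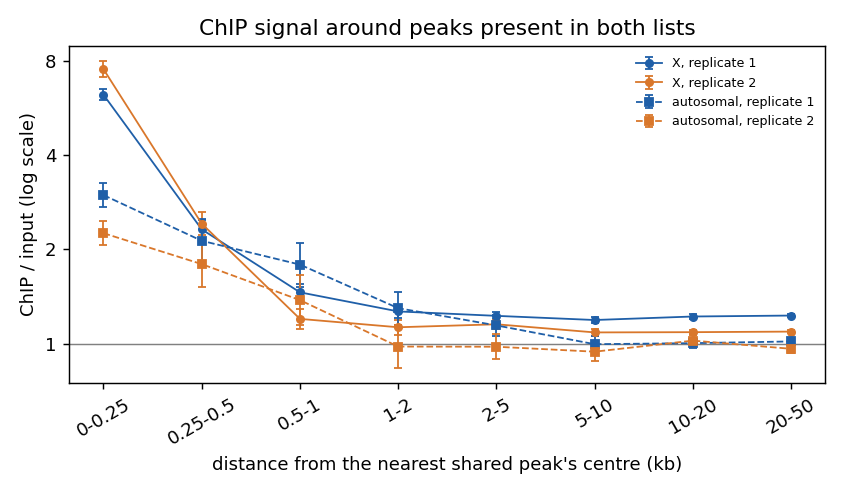
Ratio of ChIP to input reads, scaled to autosomal totals, on a log axis (y) by distance in kb from the nearest peak centre (x), for 102 X peaks (circles) and 20 autosomal peaks (squares) present in both lists, with bars for 95% counting intervals and 1 colour per replicate. X ratios fall from 6.23 and 7.52 to a level of 1.23 and 1.09, whereas autosomal ratios reach 1.02 and 0.964.

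The 12 bp recruitment sequence TCGCGCAGGGAG marked the strongest X peaks. With up to 2 mismatches it occurred in 25 of 371 X peaks (6.74%) and in 19 of 3710 random X windows (0.512%), an odds ratio of 14.0 (Fisher exact test, two-sided p = 1.20e-15). Autosomal peaks held it in 2 of 222 cases (0.901%), fewer than X peaks (Fisher exact p = 0.000752). In the better-scoring part of each list it was in 22 of 209 X peaks (10.5%) and 2 of 64 autosomal peaks (3.12%), which did not pass the threshold (Fisher exact p = 0.0786). The sequence was concentrated at the top of the lists: 9 of the 10 best X peaks had it in each replicate, against 6 of the 240 X peaks ranked from 101 to 340 in replicate 1.

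Close copies of the sequence were enriched in ChIP on X and not on autosomes. The rebuilt sequence held 3 exact copies at 2 sites, all on X and all inside peaks of both lists, with median ChIP to input folds of 26.2 and 19.0 in 500 bp windows. Of 32 X copies with up to 1 mismatch 19 lay in a peak, but several shared one. Merged within 500 bp, the copies formed 27 X sites, of which 14 (51.9%) lay in a peak, against 0 of 35 autosomal sites (Fisher exact test, two-sided p = 6.90e-07). The 35 autosomal copies had median folds of 0.870 and 0.918, and the 29 X copies with 1 mismatch had 3.47 and 3.43. These medians are per copy and not per merged site, so sites with several copies weigh more. With 1 mismatch, X held 2.27 copies per Mb and the autosomes 0.632. With 2 mismatches, copies were no denser on X, at 16.8 per Mb against 18.7, and the 215 X copies had median folds of 1.23 and 1.20 against 0.933 and 1.02 for the 1037 autosomal ones.

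**Figure D4:**
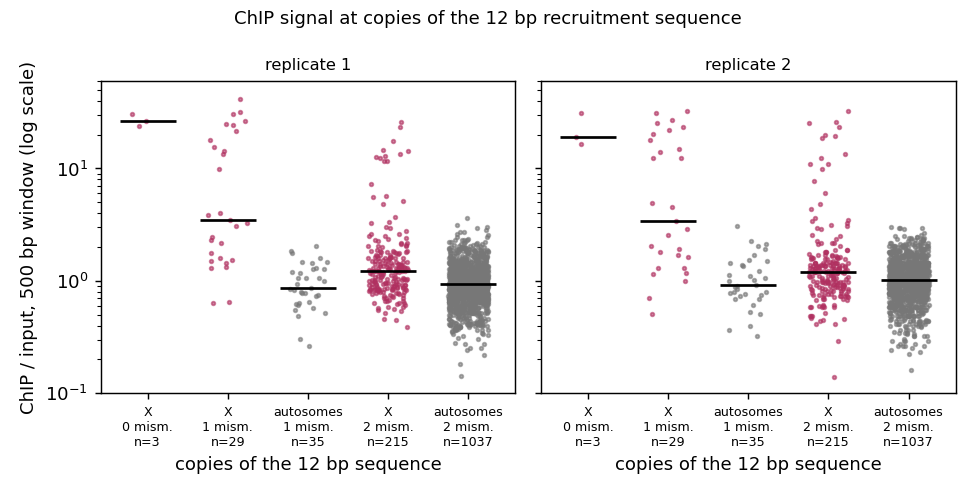
ChIP to input ratio in the 500 bp window around each copy of the 12 bp sequence (y axis, log scale), by chromosome class and number of mismatches (x axis), with 1 point per copy, 1 panel per replicate and black lines at medians. The 3 exact X copies have medians of 26.2 and 19.0, while the 35 autosomal copies with 1 mismatch have 0.870 and 0.918.

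Depth was raised in 5 regions, found after the data were seen. Both inputs showed 33926 bp of raised depth at III 3802947 to 3836872, at 31.7 and 21.3 times the autosomal median, and the ChIP libraries had 8.83 and 15.04 times that median. Its rebuilt sequence encodes GPNGSGKS and, further along the same strand, LSGGEK, which are signatures of SMC ATPases, the class to which DPY-27 belongs. With 1 read per position the depths were 17.9 and 18.8 in the inputs and 7.92 and 15.3 in ChIP. A 3383 bp stretch at I 15064125 was between 117 and 183 times the median in the 4 libraries. With 1 read per position it was 90.6 and 116 times the median in ChIP and 35.6 and 58.8 times in input, so its ChIP to input ratio depends on how repeated reads are counted. A bin holds a limited number of positions, so this count is capped soonest in the deeper inputs, here and in the region on III. It cannot show whether ChIP exceeded input in the stretch on I. ChIP replicate 1 alone was deep at II 8731260 to 8735335, at 91.0 times the median against 1.80 in ChIP replicate 2, and at X 11460587 to 11473527, at 4.10 against 1.47. ChIP replicate 2 alone was deep at I 7200004 to 7229814, at 4.62 against 1.41. In the 2 regions where the inputs were raised, ChIP depth does not measure occupancy alone. The replicate 1 list had 6 X peaks and 2 autosomal peaks in the 5 regions, and the replicate 2 list had 13 autosomal peaks.

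**Figure D5:**
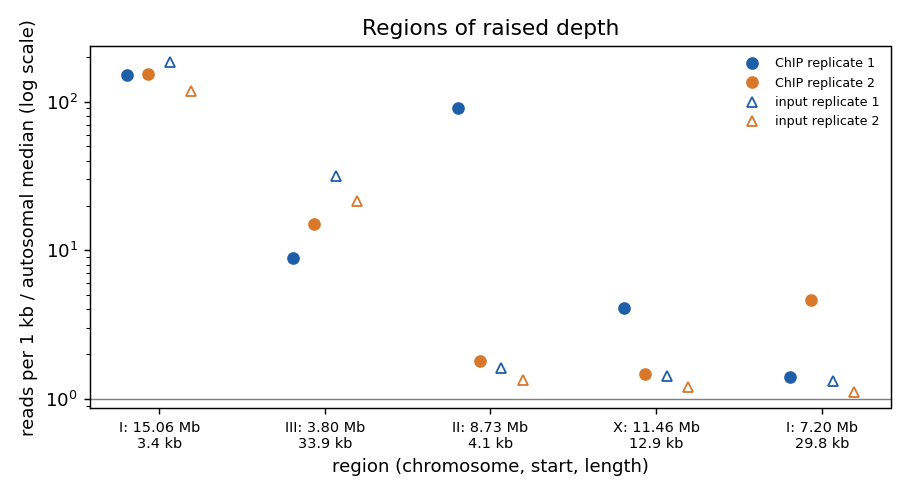
Reads per 1 kb relative to the autosomal median (y axis, log scale) in the regions of raised depth (x axis, chromosome, start and length), for ChIP (filled circles) and input (open triangles), with 1 colour per replicate. The region on III is deeper in the inputs, at 31.7 and 21.3, than in ChIP, and the region on II is raised only in ChIP replicate 1, at 91.0.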

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

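The tests of the region on II were chosen after it was seen. Among reads without a match, which entered no comparison, bla reads (ampicillin resistance, a plasmid gene) numbered 253 in ChIP replicate 1, or 224.6 per 1000000 unique nuclear reads (counting interval 198 to 254), against 3 reads (0.586 on this scale) in input replicate 1 and 0 in input replicate 2, which allows up to 1.51. ChIP replicate 2 held 5 such reads, or 5.304 on the same scale, and its interval of 1.72 to 12.4 began just above the upper limit of 1.71 in input replicate 1. Unmatched reads were 88.0% of ChIP replicate 1, so the scale matters. Per 1000000 unmatched reads bla stood at 14.6 in ChIP replicate 1 (12.8 to 16.5), 9.34 in ChIP replicate 2 (3.03 to 21.8) and 1.65 in input replicate 1 (0.341 to 4.83), and the 0 reads of input replicate 2 allow up to 14.4.

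The 4076 bp region on II raised in ChIP replicate 1 carried the authors' highest fold in that list, 75.4, and with 1 read per position it stood at 62.1 times the median. Binding at the worms' own locus is argued against by a base change, C8733236T in chromosome coordinates, carried by 96.3% of the ChIP replicate 1 reads there (26 of 27), against 1 of 7 and 0 of 3 reads in the inputs. DNA of a plasmid with the marker allele may account for it, but this cannot be told apart from bla reads that came with other unmatched DNA: they stood at 224.6 per 1000000 unique nuclear reads, yet per unmatched read they were not clear of the limit in input replicate 2. The change turns an arginine codon into a cysteine codon in an open frame of 262 codons with a Gly-X-Y run of 21 triplets, as in cuticle collagens, and is silent in another open frame of 250 codons without such runs.

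A dominant arginine to cysteine allele of a collagen is a common marker in worm transgenesis, but the gene was not identified here. Gly-X-Y runs of 22 and 20 triplets also lay in the region on I that was raised in ChIP replicate 2.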

How the results depend on the processing

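The X against autosome medians from bins, perfectly matching reads, reads limited to 3 per position, left-out raised regions, duplicate removal combined with another choice, the set test with the replicate block, merging of neighbouring copies of the sequence, and the fold minimum with 1 read per position were alternatives chosen after the data were seen. The X share, both medians, the X share of each peak list, peak sharing and the 12 bp sequence in X peaks kept their direction under every alternative run. The peak and sequence tests also stayed past their thresholds, except that in the better-scoring part of the lists the comparison of X with autosomal peaks missed it, at 10.5% of 209 against 3.12% of 64 (Fisher exact p = 0.0786), with fewer peaks tested. The ChIP to input ratio of the X share was 1.15 and ranged from 1.11 to 1.19. The difference in bin medians was 0.22 (0.14 to 0.27), and away from peaks it was 0.20 (0.12 to 0.25). X held 60.5 to 72.1% of peaks in replicate 1 and 63.5 to 68.3% in replicate 2. Sharing ranged from 46.4 to 65.1% of the replicate 2 peaks tested and from 20.9 to 29.3% of the replicate 1 peaks tested. The sequence was in 3.77 to 23.7% of X peaks.

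The number of higher bins, 134, depended on the setting. It was 52 with libraries thinned to the smallest and 74 with perfectly matching reads, which both test fewer reads. It was 72 with the replicate block, 221 with GC offsets, 207 with GC offsets and the block, and 80 with the DESeq2 Wald test, where the cause was not tested. The other 10 settings gave 90 to 175. With a library left out it ran from 0 to 41: by edgeR 0 without ChIP replicate 1 (5202 bins at an unadjusted p under 0.05) and 0 without ChIP replicate 2 (4973 bins), 5 without input replicate 1 and 41 without input replicate 2. These fits have fewer libraries, and the lone library is assumed to vary like the other group. With the block, X bins tested as a set kept their call at the preset correlation and lost it at the estimated one (p = 0.162 against 0.0457), and the bin medians kept their direction. Mean input depth in the region on III was 26.5 times the median and 18.4 with 1 read kept per position, a count that is capped in deep regions. Not run were the alternatives for promoters, gene starts and gene lists, which need gene positions, and the use of multiply matching reads, which carry no position. The bin test had little power for small changes, since simulated 2-fold changes were called in 14% of bins at this depth and number of libraries.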

Other observations

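Tests in this part were chosen after the pattern was seen, except the evenness test of the region on I, which was fixed before its value was known. A short sequence found by the 8-mer search also recurred in X peaks. Its last bases form a run that also lies within the 12 bp recruitment sequence. Whether it is a variant of that sequence or a separate one was not tested. Of 29188 8-mers, 844 were more frequent in X peaks than in matched X windows, and AGACGCAG led, in 62 of 366 X peaks (16.9%) and 0.984% of windows (one-sided Fisher exact test, adjusted p = 2.49e-37). Its 546 counterparts of the same base composition had a median of 0.820% of peaks, and the highest of them, GAGACGCA, overlaps it. The search was repeated in the X peaks of replicate 1 alone, where AGACGCAG also led (55 of 317 peaks, 17.4%). In the X peaks of replicate 2 that replicate 1 lacked, which took no part in that search, 6 of 50 held it against 5 of 500 windows (two-sided Fisher exact p = 0.000137). It was in 1 of the 20 best X peaks of replicate 1, in 20 of the 80 ranked 21 to 100 and in 36 of the 240 below, so most peaks of each rank class lacked it, and the classes were not tested against each other.

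AGACGCAG was less common on X than on autosomes, at 32.7 against 70.9 copies per Mb of rebuilt sequence. Even so, 16.3% of its 461 X copies lay in a peak, against 0.252% of 4366 autosomal copies. The 8-mer was picked for its frequency in X peaks, and peaks were denser on X, so this contrast is no separate support. Over 2 kb from peaks, its X copies had median folds of 1.21 and 1.17, against 1.15 and 1.05 in random X windows. Autosomal peaks held it in 10 of 208 cases (4.81%) against 2.21% of autosomal windows (two-sided Fisher exact p = 0.0305). Among 17848 8-mers tested in the 208 autosomal peaks, 6 passed, led by AGAGAGAG in 18.8% of peaks. AGAGAGAG was not particular to autosomal peaks. It was also in 13.7% of X peaks against 1.61% of X windows (one-sided Fisher exact test, adjusted p = 4.66e-21).

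The 29811 bp region on I was chosen as raised in ChIP replicate 2 alone, where its depth was 4.14 times that of its input, against 1.06 times in replicate 1. Extra copies of the whole segment in the DNA of ChIP replicate 2 may account for it. Its reads, thinned to the usual depth, had an unevenness at percentile 17.02 of 2808 other autosomal stretches, so they were not unusually uneven. The other stretches were not thinned, and thinning breaks up repeated reads. The region was also chosen as a run of raised bins. Both favour evenness, so this percentile cannot decide whether extra copies were the cause. Binding in the second preparation alone was not tested.

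The region on III, taken as the transgene from its depth and SMC signatures and not from an annotation, was less deep in ChIP than in input, 0.278 times in the first pair and 0.706 times in the second. Duplicate reads as the whole cause are argued against by ratios of 0.442 and 0.8123 with 1 read per position. GFP reads stood at 0.5444 of input in the first pair (interval 0.342 to 0.866) and 0.615 in the second (0.373 to 1.01), and cat reads at 0.279 (0.152 to 0.514) and 0.777 (0.477 to 1.26). A probe read needed 20 exact bases. Only 37.8% of the unique reads of ChIP replicate 1 were free of mismatches, against 80.8% in input replicate 1, which can lower the probe ratios of that pair. Probe reads were counted with repeats. On that count the region stood at 0.278 in the first pair, inside the cat interval and under the GFP interval, and at 0.706 in the second, inside both. If GFP and cat belong to the region, which was assumed, mixing of DNA without the transgene and poorer recovery of this chromatin cannot be told apart. Both would lower the region and its probes alike, and the probe counts are small. No biological explanation was tested.

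At neighbouring positions of the region on III, counted along the chromosome from 1, reads of input replicate 1 carried T3813887C in 8 of 10 cases and A3813890C in 25 of 25. In input replicate 2 they were in 1 of 1 and 4 of 4 reads, and the ChIP libraries had 0 reads at either position. Unmatched reads had a GC content of 53.6% and 56.0% in the ChIP libraries and 45.8% and 43.6% in the inputs.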
